A study of Mus musculus with 6 samples.

How the data were processed

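RNA was taken from the whole back skin of 6 female mice of a shared litter on postnatal day 2.5. Of these, 3 carried K5cre-caNrf2, which places a constitutively active form of the transcription factor Nrf2 in keratin 5-expressing keratinocytes. The other 3 carried K5cre without the active transgene and served as controls. The background was mixed FVB/N and C57BL/6. Each mouse gave 1 array, so the n of 3 per group counts animals. Per the labels' protocols, biotinylated cRNA was made from 2 ug of total RNA for Affymetrix arrays. The genotype cell of the caNrf2 samples reads tg/g where the protocol has tg/tg, and the treatment cell names caNrf2 on the control samples too. Groups were therefore taken from the sample titles, with which the genotype cells go together.

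The values deposited by the authors are probe set intensities on a linear scale, summarised with RMA per the submitters' processing notes. RMA corrects the background, quantile-normalizes the arrays and summarises probes on a log scale, so these values had been transformed back. The RMA version and any later scaling are not given in the sources used here. The lowest intensity on an array lay between 5.63 and 5.88, the median between 80.3 and 81.6, and the highest between 20444 and 21290. Quantile normalization forces a near-equal distribution on all arrays, so a shift of most transcripts in 1 direction could not be seen. The quartiles still differed between the groups. The lower quartile was 24.9 to 25.4 in caNrf2 and 23.8 to 24.3 in control arrays. The upper quartile was 325 to 328 in caNrf2 and 334 to 341 in control arrays. Small shifts of dim or bright genes may in part reflect this difference. The number of arrays limits the precision, and no read depth applies.

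The array table lists 45101 probe sets. Of these, 34945 had 1 gene symbol, 932 had several, and 9211 had none, of which 51 were control probe sets. The array held 64 control probe sets in all, and those with a gene symbol are in none of these counts. Symbols were updated through the Entrez identifier with a RefSeq gene table of mouse assembly GRCm38.p6, in which 34741 of the single-symbol probe sets matched. The rest kept the symbol of the array annotation. That table served only for names and for gene neighbourhood, and no coordinates are given. Where a gene had several probe sets, the probe set with the highest mean over all 6 arrays stood for it, which left 18193 genes. Probe sets with no symbol or with several were tested apart and are not named by gene. No dim probe sets were removed. Of the 12 probe sets of Y-linked genes, which gauge the background in female mice, 11 had both group means under 20, and their group means ran from 6.46 to 31.0.

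Intensities were log2-transformed and fitted with limma 3.58.1 (lmFit and eBayes without an intensity trend, R 4.3.3) with group as the only term. Each gene had 4 residual degrees of freedom, to which the moderation added 5.52. P-values were two-sided and adjusted over all genes by Benjamini-Hochberg, and a gene was called changed at an adjusted p under 0.05. Errors of log2 fold changes are standard errors (SE) from the fit, and levels are mean intensity ± SD. On simulated log2 values with the real gene means and spreads, 200 of 18193 genes were changed. The fit recovered 18% of the genes changed by 0.25 on the log2 scale, 84% of those changed by 0.5, 98% of those changed by 1 and 100% of those changed by 2. Of all simulated calls, 5.06% were false. Each gene was drawn independently, so deviations that genes share on an array were not simulated and this share need not hold here.

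The 40 gene lists were written before the data were examined, for Nrf2 biology, keratinocyte and follicle programmes and the other cell types of skin. Of 641 list entries, 571 matched a measured gene, and the others are not analysed here. Lists were tested with camera in limma at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 40 lists. They were tested again with an estimated correlation, which gave a larger p for each list that had passed. With an estimated correlation camera takes its p from the 4 residual degrees of freedom, which raises p at any correlation. The lists were also tested with fry, which asks whether the members of a list move on balance in 1 direction. None of the lists passed with an estimated correlation, so that adjusted p stands beside each list that passed at the preset value. Gene families sharing a symbol stem, 570 with at least 5 measured members, were tested for an excess of called genes by a hypergeometric test, adjusted by Benjamini-Hochberg within each direction. The family test was added after the data were examined.

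Genes are named by a rule fixed before the data were examined. It takes Nfe2l2, the 12 largest rises and the 12 largest falls among called genes whose groups did not overlap, leaving out uncharacterised symbols, and up to 4 members with the smallest p of each list. Any other gene is said to have been chosen after its values were seen. The alternatives were a further quantile normalization, centring of each array on its median, a filter on dim probe sets, averaging of a gene's probe sets, every probe set on its own, an intensity trend with robust variances, array weights, a fold of at least 2, an adjusted p under 0.10, a block on the replicate number, an equal-variance test without moderation, omission of each array in turn, and a pseudocount of 16 before the logarithm.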

Results

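Whole back skin of 3 caNrf2 and 3 control littermates was profiled on postnatal day 2.5. The series title states the aim of identifying target genes of Nrf2 in skin, and the comparison of both genotypes answers which transcripts differed when Nrf2 was constitutively active in keratinocytes. Pearson correlations of log2 intensity ran from 0.9976 to 0.998 between caNrf2 arrays, from 0.9973 to 0.9977 between control arrays, and from 0.9949 to 0.9962 between the groups. The principal component with the largest share carried 58.1% of the variance and separated the groups. The ratio of 3' to 5' control probe sets, a sign of RNA quality, differed little. It was 0.493 ± 0.012 in control and 0.525 ± 0.011 in caNrf2 skin for Actb on the log2 scale (SD, n = 3; exact two-sided permutation p = 0.1, the smallest that 3 against 3 arrays allow). For Gapdh the exact p was 0.2.

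Skin with active Nrf2 carried more RNA of many detoxification, glutathione and NADPH enzymes, and less RNA of some hair fibre proteins. As lists, detoxification, glutathione, NADPH and hair keratin genes passed camera at the preset correlation, but had adjusted p = 0.172, 0.18, 0.234 and 0.292 with an estimated correlation. In limma with Benjamini-Hochberg adjustment, 412 of 18193 genes were higher and 252 were lower in caNrf2 skin. The rises were larger than the falls. A fold of at least 2 was reached by 61 of the higher and 14 of the lower genes, and a fold of at least 4 by 21 and 2. The groups did not overlap in 100% of the called genes and in 25.7% of all genes, where chance gives 10%. The counts depended on single arrays. The higher count was 244 without caNrf2 replicate 3, 226 without control replicate 1 and 265 without control replicate 3. The lower count was 145, 131 and 95 without caNrf2 replicates 1, 2 and 3, and 72 without control replicate 1.

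Nfe2l2, the gene coding for Nrf2, rose from 775 ± 49.5 to 1200 ± 56.4 (mean intensity ± SD, n = 3), a log2 fold change of 0.63 ± 0.07 (SE; limma, adjusted p = 0.000736). Whether this probe set also detects the transgene transcript was not determined. A dim Nfe2l2 probe set read 18.0 ± 0.976 and 20.2 ± 1.56 and did not pass. Of the 10 measured genes of the Nrf2 pathway list, 5 rose, 0 fell and 5 did not pass, and 5 also passed when adjusted over the list alone. The small Maf protein Mafg, a DNA-binding partner of Nrf2, rose by 0.72 ± 0.06, and the autophagy receptor Sqstm1 by 0.54 ± 0.06. Keap1, the adaptor that targets Nrf2 for degradation, rose by 0.37 ± 0.06 (limma, adjusted p = 0.0104), and the repressor Bach1, chosen after its values were seen, by 0.32 ± 0.07 (adjusted p = 0.0404). The Bach1 call was lost with any of 5 arrays left out, all but caNrf2 replicate 2, at adjusted p up to 0.127. The list passed camera (median 0.23, adjusted p = 0.00214), but had an adjusted p = 0.296 with an estimated correlation.

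The glutathione and thioredoxin system had the highest median of all lists. Gpx2, a glutathione peroxidase, rose from 109 ± 13.9 to 2465 ± 116, and Srxn1, which repairs oxidised peroxiredoxins, from 144 ± 13.7 to 3047 ± 140 (mean intensity ± SD, n = 3). Their log2 fold changes were 4.51 ± 0.09 and 4.41 ± 0.08 (limma, adjusted p = 4.94e-09 and 2.23e-09). The 4 probe sets of Srxn1 ranged from 0.84 to 4.41. Slc7a11, the cystine importer that feeds glutathione synthesis, rose by 3.41 ± 0.12 from a control mean of 30.7 at the top of the range of Y-linked probe sets, and thioredoxin reductase Txnrd1 by 1.22 ± 0.06. The glutamate-cysteine ligase subunits Gclc and Gclm, chosen after their values were seen, rose by 1.61 ± 0.08 and 1.51 ± 0.08. Of 14 measured members, 9 rose, 1 fell and 4 did not pass, with the same counts adjusted over the list alone. The member that fell was Chac1, a glutathione-degrading enzyme, at -0.35 ± 0.07 (limma, adjusted p = 0.0344). Its call was lost without any of 5 arrays, all but control replicate 3, at adjusted p up to 0.129. The list median was 1.21 (camera adjusted p = 1.41e-15), with adjusted p = 0.18 with an estimated correlation.

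Detoxification enzymes rose as a group, 22 of 32 measured genes being higher, 0 lower and 10 not passing. Adjusted over the list alone, 27 were higher and 1 was lower. Nqo1, the quinone reductase, rose from 67.7 ± 4.36 to 1419 ± 99.3 (log2 fold change 4.39 ± 0.07; limma, adjusted p = 2.23e-09). The glutathione S-transferase Gsta3 rose by 6.17 ± 0.14 on the log2 scale. Its control mean of 15.8 lay within the range of Y-linked probe sets, and its second probe set gave 2.62, so the size of its rise and its rank are uncertain. Gsta4 rose by 3.06 ± 0.10, Gstm1 by 2.53 ± 0.07, the aldehyde dehydrogenase Aldh3a1 by 2.66 ± 0.14 and the carbonyl reductase Cbr3 by 2.49 ± 0.07. The list median was 0.96 (camera adjusted p = 7.34e-42), with adjusted p = 0.172 with an estimated correlation. Aldh3a1 was the only called gene among 7 measured targets of the aryl hydrocarbon receptor. That list did not pass (adjusted p = 0.91), its median of -0.06 lying opposite to its mean of 0.30. Adjusted over that list alone, 1 gene was higher and 2 were lower.

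NADPH supply rose in parallel. In this list 4 of 6 genes rose, 0 fell and 2 did not pass, with the same counts adjusted over the list alone. Pgd and Taldo1, enzymes of the pentose phosphate pathway, rose by 1.42 ± 0.06 and 1.07 ± 0.07, malic enzyme Me1 by 0.83 ± 0.06 and transketolase Tkt by 0.44 ± 0.06 (limma, adjusted p at most 0.00222). The list median was 0.64 (camera adjusted p = 7.96e-07), with adjusted p = 0.234 with an estimated correlation. Of 9 efflux transporters, 4 rose, 0 fell and 5 did not pass, again with the same counts adjusted over the list alone. Abcc4 rose by 2.58 ± 0.07, Abcc3 by 2.36 ± 0.06, Abcb6 by 0.89 ± 0.09 and Abcc1 by 0.68 ± 0.06. The efflux list passed as higher (camera adjusted p = 0.000832; mean 0.68) although its median was -0.02, and had adjusted p = 0.321 with an estimated correlation. Of 7 genes of iron and haem handling, 4 rose, 0 fell and 3 did not pass, and 5 were higher adjusted over the list alone. Biliverdin reductase Blvrb rose by 2.03 ± 0.07, haem oxygenase Hmox1 by 1.22 ± 0.08, the haem transporter Slc48a1 by 0.62 ± 0.06 and ferritin heavy chain Fth1 by 0.28 ± 0.06. The Fth1 call was lost without any of the 6 arrays, at adjusted p from 0.0526 to 0.106. The iron list median was 0.28 (camera adjusted p = 1.03e-08), with adjusted p = 0.234 with an estimated correlation.

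**Figure D1:**
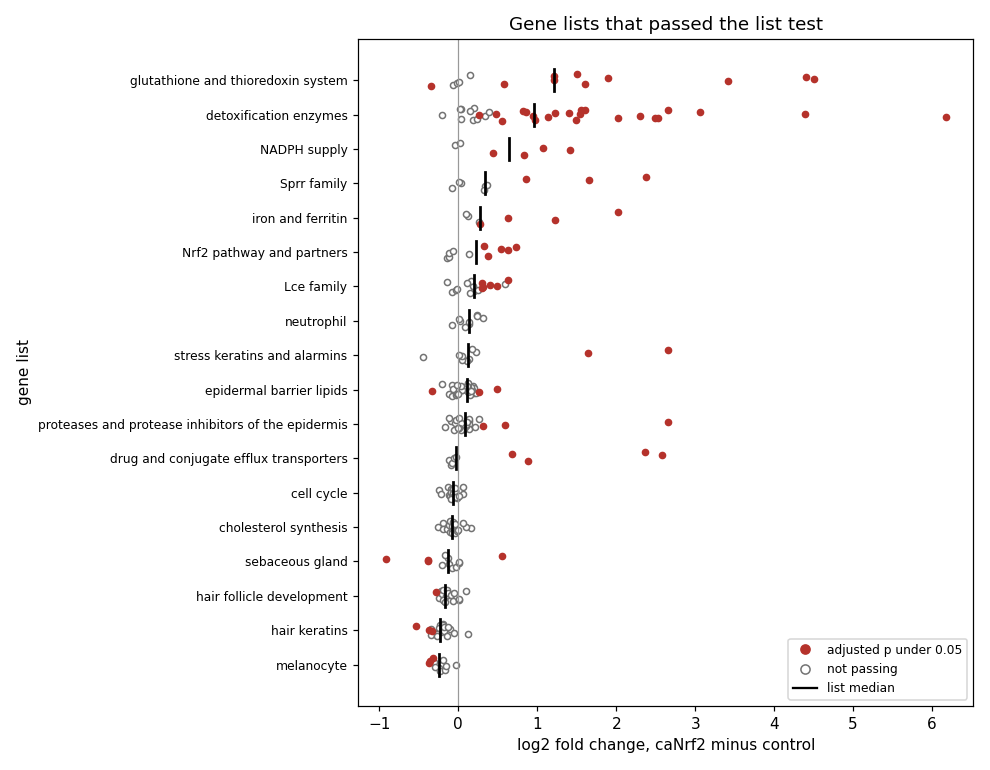
Log2 fold change (caNrf2 minus control, horizontal axis) of each measured member of the 18 gene lists that passed camera, with filled points for genes at an adjusted p under 0.05, open points for the others and a black line at the list median. The glutathione and thioredoxin system had the highest median, 1.21, and the melanocyte list the lowest, -0.24.

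Among the other genes with the 12 largest rises, Adh7, an alcohol dehydrogenase active on retinol, rose by 3.46 ± 0.11, the iron-binding protein Pir by 2.98 ± 0.09 and Fbxo2, a subunit of a ubiquitin ligase, by 2.91 ± 0.12 (limma, adjusted p at most 5.22e-07). The control mean of Fbxo2, 29.9, lay within the range of Y-linked probe sets, so the size of its rise is uncertain. The protease inhibitor Slpi rose from 123 ± 25.2 to 766 ± 118, a log2 fold change of 2.65 ± 0.16 (n = 3; limma, adjusted p = 9.52e-06).

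Genes of the cornified envelope, the protein shell of the outermost keratinocytes, were higher in part. Sprr2d rose from 110 ± 1.54 to 575 ± 60.3 and Sprr2h from 677 ± 28.0 to 2135 ± 94.2, log2 fold changes of 2.38 ± 0.08 and 1.66 ± 0.06 (n = 3; limma, adjusted p at most 3.2e-07). Of 9 Sprr genes measured, 3 rose, 0 fell and 6 did not pass, and 6 were higher adjusted over the list alone. The third rise was that of Sprr2f, whose means lay within the range of Y-linked probe sets in both groups. Whether Sprr2 probe sets also detect related members was not tested. The median was 0.34 (camera adjusted p = 3.93e-06), with adjusted p = 0.18 with an estimated correlation. The study may have followed up Sprr2 genes, Slpi and Epgn in caNrf2 skin (from memory, not from the data used here), so their direction is not taken as independent evidence. In the list of Lce genes with Kprp and Crct1, 6 of 17 genes, Kprp among them, rose, 0 fell and 11 did not pass, and 10 were higher adjusted over the list alone. Lce3f rose by 0.63 ± 0.07, Lce3c by 0.49 ± 0.07 and Lce1d by 0.40 ± 0.06. The median of this list was 0.20 (camera adjusted p = 2.4e-06), with adjusted p = 0.321 with an estimated correlation.

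Markers of keratinocyte differentiation moved both ways. Of 26 measured, 2 rose, 3 fell and 21 did not pass, and 3 were higher and 3 lower adjusted over the list alone. Krt78 rose by 0.48 ± 0.06 while Krt77 fell to -0.61 ± 0.08, the envelope precursor Ivl (involucrin) to -0.55 ± 0.08 and Tchhl1 to -0.45 ± 0.06 on the log2 scale (limma, adjusted p at most 0.0043). This list did not pass camera (adjusted p = 0.433). Among 12 genes of basal keratinocytes, Krt15 fell, at -0.30 ± 0.06 (limma, adjusted p = 0.0209), 11 did not pass, and 1 was higher and 1 lower adjusted over the list alone. The Krt15 call was lost without caNrf2 replicate 1 or 3 or control replicate 1 or 2, at adjusted p up to 0.0824, and the list did not pass (camera adjusted p = 0.721).

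Krt16, a keratin of stressed epidermis, rose from 563 ± 58.2 to 1763 ± 221, a log2 fold change of 1.64 ± 0.10 (n = 3; limma, adjusted p = 1.49e-05). Krt16 and Slpi were the 2 genes that rose among 10 stress keratins and alarmins, 0 fell and 8 did not pass, with the same counts adjusted over the list alone. Krt6a, the usual partner of Krt16, gave 0.13 ± 0.07 (adjusted p = 0.307). The list passed (camera adjusted p = 0.00192; median 0.12), with adjusted p = 0.326 with an estimated correlation and 0.0743 without caNrf2 replicate 2. Of 26 epidermal proteases and inhibitors, 3 rose, 0 fell and 23 did not pass, and 5 were higher adjusted over the list alone. Besides Slpi these were Serpinb6c (0.59 ± 0.10) and Serpinb12 (0.31 ± 0.06), both intracellular serpins. Serpinb6c lost its call without control replicate 3 (adjusted p = 0.0544), and Serpinb12, whose other probe set gave 0.11, without any array but control replicate 3 (up to 0.115). This list passed (median 0.08, camera adjusted p = 0.00942), with adjusted p = 0.259 with an estimated correlation.

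Of 24 cytokines and chemokines, 3 were higher. Il1f9, also named Il36g, rose from 560 ± 6.91 to 2467 ± 230, a log2 fold change of 2.14 ± 0.07, and Il1f8, also named Il36b, by 0.59 ± 0.06 (n = 3; limma, adjusted p at most 0.000545). The third was Il24, whose means of 18.0 and 25.4 lay in the range of Y-linked probe sets in both groups. Its call was lost without caNrf2 replicate 3 or control replicate 1 or 3, at adjusted p up to 0.1. None fell, 21 did not pass, and 5 were higher adjusted over the list alone. The cytokine list did not pass (camera adjusted p = 0.0736), but did in 6 alternatives, at 0.0302 without caNrf2 replicate 3, 0.0436 without control replicate 2, 0.0213 with fry, 0.0426 with an intensity trend, 0.0415 with array weights and 0.0356 with log2(value + 16). Epgn, a ligand of the EGF receptor, rose by 0.66 ± 0.09 (adjusted p = 0.00255). It was the only called gene among 7 such ligands, of which 3 were higher and 1 lower adjusted over the list alone (camera adjusted p = 0.305; median -0.00, mean 0.12). Of 16 immediate early genes only Fosl1, a subunit of AP-1, rose, by 0.93 ± 0.09 (limma, adjusted p = 0.000277), also when adjusted over the list alone (camera adjusted p = 0.201).

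**Figure D2:**
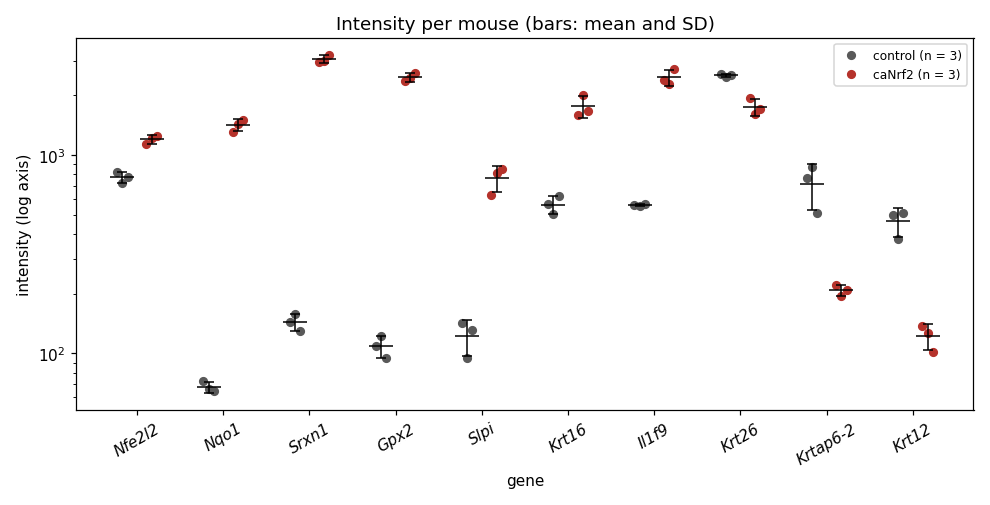
Intensity on a log axis of 10 named genes in each of the 3 control (grey) and 3 caNrf2 (red) mice, with the mean and SD as black bars. Nqo1 lay at 67.7 ± 4.36 in control and 1419 ± 99.3 in caNrf2 skin, and Krt12 at 463 ± 75.9 and 122 ± 18.1.

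The largest falls were in hair fibre genes. Of the 12 named, 10 were keratin-associated proteins (Krtap), which cross-link keratin filaments in the hair shaft. Krtap6-2 fell from 715 ± 186 to 209 ± 13.5, Krtap19-2 from 993 ± 373 to 272 ± 36.2 and Krtap21-1 from 1217 ± 194 to 458 ± 51.5 (mean intensity ± SD, n = 3). Their log2 fold changes were -1.74 ± 0.16, -1.80 ± 0.26 and -1.40 ± 0.12 (limma, adjusted p at most 0.00431). Krtap6-3 (-2.62 ± 0.19) and Krtap19-1 (-2.55 ± 0.30) had larger estimates, but their other probe sets gave -0.26 and -0.25, and Krtap6-3 reached 27.6 in caNrf2 skin, within the range of Y-linked probe sets. Krtap19-3, Krtap19-4, Krtap19-5, Krtap19-9b and Krtap6-5 lay between -1.35 and -1.11. With an intensity trend and robust variances Krtap19-1, Krtap19-2, Krtap19-4 and Krtap19-5 did not pass, at adjusted p from 0.0552 to 0.0841. The remaining falls were Krt12, a keratin best known from cornea (-1.92 ± 0.14, with both probe sets alike), and the acyl-CoA synthetase Acsl6 (-1.25 ± 0.08), whose other probe set gave 0.10. By family, 19 of 38 Krtap genes were lower and 1 was higher (hypergeometric test, adjusted p = 3.92e-23 for lower), with a median of -0.42. Whether these probe sets also detect related Krtap genes was not tested, and genes that share signal would repeat each other in this count and p. Control replicate 3 stood apart in these genes, with a median over the 38 of -0.23 from the control mean against 0.11 and 0.12 in control replicates 1 and 2. Without it 29 were lower, against 14 without control replicate 1 or 2.

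Hair keratins, the filament proteins of the same fibre and of the inner root sheath, were lower as a list. Of 20 measured, 3 fell, 0 rose and 17 did not pass, and 13 were lower adjusted over the list alone. Krt26 fell to -0.53 ± 0.08, Krt75 to -0.37 ± 0.06 and Krt72 to -0.33 ± 0.07 (limma, adjusted p = 0.00425, 0.00613 and 0.0325). Of these, Krt26 and Krt72 are keratins of the inner root sheath. The fibre keratin Krt35 did not pass (-0.25 ± 0.06; limma, adjusted p = 0.0549). Krt72 lost its call without caNrf2 replicate 2 or 3 or control replicate 1 or 2, at adjusted p up to 0.126. The list median was -0.23, against -0.42 for the Krtap genes. The list passed camera (adjusted p = 7.56e-09), with adjusted p = 0.292 with an estimated correlation. Genes of hair follicle development shifted by a like amount, with Shh, a signal from the hair matrix, as the 1 call among 21 (-0.28 ± 0.06; limma, adjusted p = 0.0358) and 8 genes lower adjusted over the list alone. The Shh call was lost without any of the 6 arrays, at adjusted p from 0.0604 to 0.129. The list median was -0.17 (camera adjusted p = 2.36e-05), with adjusted p = 0.259 with an estimated correlation. Melanocyte genes were lower too, with 3 of 11 called, 0 higher and 10 lower adjusted over the list alone. The melanosomal proteins Mlana (-0.38 ± 0.09) and Gpr143 (-0.32 ± 0.07) and their regulator Mitf (-0.36 ± 0.08) each lost the call without any of 5 arrays, at adjusted p up to 0.158, and with a further quantile normalization, at 0.0607 to 0.0652. The melanocyte median was -0.24 (camera adjusted p = 2.4e-06), with adjusted p = 0.283 with an estimated correlation. Control replicate 3 was also the lowest control for the hair keratins, with a median of -0.09 from the control mean. The Actb 3'/5' log2 ratio differed between the groups by 0.0323.

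**Figure D3:**
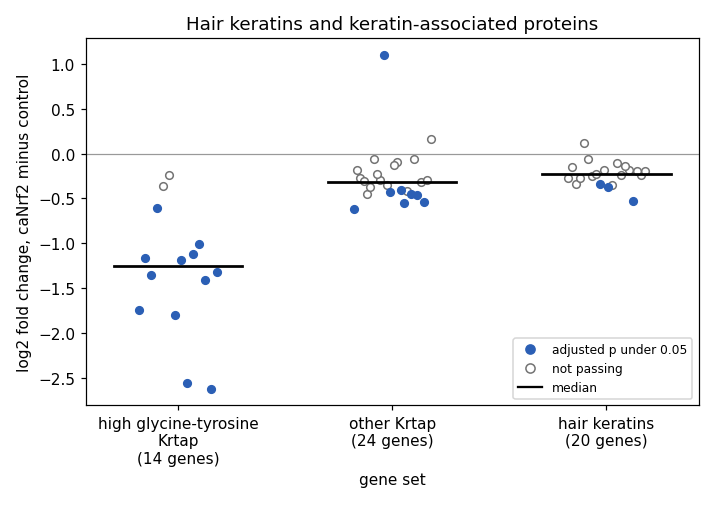
Log2 fold change (caNrf2 minus control, vertical axis) of 14 high glycine-tyrosine Krtap genes (a subset chosen after its values were seen), 24 other Krtap genes and 20 hair keratins, with filled points for genes at an adjusted p under 0.05 and black lines at the medians. The medians were -1.25, -0.31 and -0.23.

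Sebaceous and barrier lipid lists had smaller median shifts than the hair keratin, follicle and melanocyte lists. Of 12 sebaceous gland genes, 3 fell, 1 rose and 8 did not pass, with 4 lower and 1 higher adjusted over the list alone. The desaturase Scd3 fell to -0.92 ± 0.11, the elongase Elovl3 to -0.38 ± 0.07 and the fatty acyl reductase Far2 to -0.39 ± 0.08, while Mgst1, also on the detoxification list, rose by 0.55 ± 0.06 (limma, adjusted p at most 0.0273), although its other probe set gave 0.06. Elovl3 lost its call without caNrf2 replicate 3 or control replicate 1 (up to 0.0674), and Far2 without any array but control replicate 3 (up to 0.0855). The sebaceous list passed (median -0.13, camera adjusted p = 0.00942), with adjusted p = 0.456 with an estimated correlation. Of 29 epidermal barrier lipid genes, Cyp4f39 (0.48 ± 0.06) and the ceramide synthase Cers3 (0.27 ± 0.06) rose, Elovl6 (-0.33 ± 0.07) fell and 26 did not pass, and 5 were higher and 1 lower adjusted over the list alone. Cers3 lost its call without any of the 6 arrays (0.0516 to 0.163), and Elovl6, with probe sets from -0.46 to -0.11, without any of 4 (up to 0.127). The barrier list passed as higher (median 0.11, camera adjusted p = 0.0157), with adjusted p = 0.259 with an estimated correlation and 0.053 without caNrf2 replicate 3.

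The other lists that passed camera had 0 called genes. Cholesterol synthesis was lower (20 genes, median -0.08, camera adjusted p = 0.0448), with adjusted p = 0.494 with an estimated correlation and up to 0.161 without any of 4 arrays. Cell cycle genes were lower (24 genes, median -0.06, camera adjusted p = 0.0258), with adjusted p = 0.259 with an estimated correlation and 0.0618 without caNrf2 replicate 1. Neutrophil genes were higher (9 genes, median 0.13, camera adjusted p = 0.0367), with 2 higher adjusted over the list alone. That list had adjusted p = 0.263 with an estimated correlation and up to 0.0701 without caNrf2 replicate 1 or 3 or control replicate 3.

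Other cell types and programmes did not pass camera. Junction genes (18, camera adjusted p = 0.0793) held 2 falls, also 2 adjusted over the list alone, in the desmosomal cadherin Dsc2 (-0.67 ± 0.07) and in Cldn8 (-0.28 ± 0.06). The other Dsc2 probe set gave -0.18. This list passed in 4 alternatives, at 0.0302 without caNrf2 replicate 3, 0.0436 without control replicate 2, 0.027 with a further quantile normalization and 0.0208 with fry, and Cldn8 lost its call without any of the 6 arrays (0.057 to 0.119). Of 12 adipocyte genes only the hormone gene Lep fell, at -0.58 ± 0.07 (limma, adjusted p = 0.000946; camera adjusted p = 0.943), and 1 was higher and 1 lower adjusted over the list alone. Among 10 dendritic and Langerhans cell genes, Cd207 rose (0.36 ± 0.08) and Epcam fell (-0.32 ± 0.06), each 1 of 2 per direction adjusted over the list alone (camera adjusted p = 0.359). Cd207 lost its call without any of the 6 arrays (0.0521 to 0.109) and Epcam without any of 5 (up to 0.0907), and the other Epcam probe set gave 0.09, with adjusted p = 0.238 for the average of both. Of 18 genes of the heat shock and unfolded protein responses, Chac1 alone was called, with 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.943). The lists with 0 calls over all genes and camera adjusted p of 0.14 to 0.943 were those of endothelium (0.14), skeletal muscle (0.161), clock outputs (0.208), mast cells (0.213), fibroblasts and dermal matrix (0.283), Y-linked genes (0.366), red cells (0.433), interferon response (0.754), macrophages (0.83), nerve (0.91), cartilage and bone (0.91) and T cells (0.943). Adjusted over the list alone, 2 T cell genes were lower and no gene of the other 11 lists passed. The muscle list passed at 0.0286 without control replicate 2, and the mast cell list at 0.0373 without caNrf2 replicate 1. At an unadjusted p under 0.05, 3706 of all genes passed limma.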

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

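Of the tests in this part, only the splits of the arrays were chosen before their result was seen. Probe sets without a gene symbol, which the gene comparison leaves out, carried a difference between the groups: 47 of 9160 were higher in caNrf2 skin and 29 lower (limma, every probe set tested). The largest rise was 2.31 ± 0.12 on the log2 scale, from a mean intensity of 44.2 to 220 (adjusted p = 3.43e-06).

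Dividing the 6 arrays otherwise into 3 and 3 bears on both counts. For the 412 higher genes and for the 252 lower genes alike, the real division was the only 1 of the 10 possible to call as many, and the highest count among the others was 0. With 10 divisions no share under 0.05 can arise.

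Krtap genes fell by a median of -0.42 over 38 genes, unevenly, with -1.06 in the 20 at 1 locus, singled out after their values were seen, and -0.39 in the 18 outside it, against -0.23 in the hair keratins. At the locus 12 of the 20 were called lower, and 12 of the 14 high glycine-tyrosine genes were. Outside the locus 7 were called lower, as were 7 of the 24 Krtap genes of other classes. The falls at the locus were thus largely those of the high glycine-tyrosine class. Less hair shaft RNA as a whole would lower Krtap genes about as much as the hair keratins, a list that also holds inner root sheath keratins. But 6 of the 20 at the locus, 2 of them with discordant probe sets, had an upper 95% bound below its lowest estimate. That estimate was -0.53, for Krt26 of the inner root sheath. The bound was adjusted over all 38, and 5 to 11 genes met this with 1 array left out. Outside the locus 0 genes met it, and this explanation stays open there. Mice in a steep phase of hair growth may differ most in late fibre genes, and across the 38 genes the spread among control mice went with the fall (Spearman rho = -0.541, permutation p = 6e-04), but without control replicate 3 rho was -0.107, so the relation depends on 1 mouse and stays open. For the genes at the locus a strain variant near them cannot be told apart from an effect of the transgene, since no Krtap gene elsewhere fell by more than -0.62, and 2 of its 20 other neighbours were called, Bach1 (higher) and Cldn8 (lower), against 3.65% of all genes (binomial p = 0.164). It would not bring the 7 falls among the 18 Krtap genes outside the locus.

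Hair keratin, follicle development and melanocyte genes were lower together at the preset correlation (median -0.19 over 52 genes, of which 7 passed on their own), with adjusted p = 0.292, 0.259 and 0.283 with an estimated correlation. A normalization shift caused by strongly induced genes would vanish on scaling each array to the fibroblast genes. The median then was -0.127, against -0.19 before, so part of the fall went with the scaling and part stayed. The bootstrap 95% interval of -0.161 to -0.11 resamples genes and not mice, so it does not measure the spread between mice. A lower share of follicle in the sampled skin stays open. The medians of the 3 lists lay within 0.0696 of each other (permutation p = 0.0882), and no fibroblast, muscle, endothelial or macrophage list had a median below -0.05, yet the members differed beyond their errors (Cochran Q per degree of freedom 2.9, against 1.8 at the 95th percentile of 10000 simulations of errors alone). Genes also expressed outside follicles would fall less, which was not measured, and a delay of hair growth in caNrf2 mice was not tested.

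Slpi, Krt16, Sprr2d, Sprr2h and Il1f9 rose without the usual companions of Krt16. In a wound-like stress response of the whole epidermis the other members of the stress list would rise with Krt16, but 5 of the 5 above the level of Y-linked genes had an upper 95% bound under 0.82, which is 0.5 times the log2 rise of Krt16. These were Krt6a, Krt6b, Krt17, S100a8 (0.05, 95% interval -0.18 to 0.28) and S100a9 (0.11, -0.20 to 0.42), most of them chosen after their values were seen. Krt6a already stood at 2365 in control skin, against 563 for Krt16. In whole skin a rise in some cells gives a smaller fold change against a higher baseline. The comparison therefore does not exclude a stress response in part of the epidermis. It covers the stress list alone. Fosl1, Epgn and Il1f8 of other lists rose and were left out of it, as were the members of those lists that did not pass. Neutrophils in the skin would bring their abundant transcripts. Of the neutrophil list only Camp lay above 2 times the highest Y-linked level, and S100a8 and S100a9, which stand on the stress list, were added. The highest upper bound among these 3 was 0.421, against 1.33 for 0.5 times the rise of Slpi. The comparison thus rests on 1 gene of the neutrophil list. A small number of neutrophils stays open. Of 9 neutrophil genes, most of them near the Y-linked level, 8 lay above 0 (camera adjusted p = 0.0367, and 0.263 with an estimated correlation). But 3 of the 4 measured Y-linked genes, the gauge of background, lay above 0 too. Their median was 0.09, against 0.13 for the neutrophil list, so these small rises need not come from neutrophils. A direct effect of Nrf2 on Slpi, Krt16, Sprr2d, Sprr2h and Il1f9 remains a hypothesis that these arrays do not test.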

How the results depend on the processing

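All alternatives were chosen before the data were examined. Nfe2l2 stayed higher and past the threshold in each of the 14 alternatives run for it. Of 18 alternatives for the counts, 6 moved the 412 higher genes and 9 the 252 lower genes by over 1.5 times. A fold of at least 2 left 61 and 14 by construction, an adjusted p under 0.10 gave 719 and 528, and the equal-variance test without moderation, which estimates each spread from 6 arrays, gave 119 and 20. Lower genes numbered 415 with dim probe sets removed, of which 205 were among the 252, and 500 with an intensity trend and robust variances, of which 240 were; the cause was not tested. With 1 array left out, which also removes samples, the counts ran from 226 to 316 and from 72 to 196. Of the 18 lists that passed camera, 0 passed with an estimated correlation, at adjusted p = 0.172 for detoxification enzymes, 0.18 for glutathione and Sprr genes, 0.234 for NADPH supply, 0.259 for follicle development, 0.283 for melanocytes, 0.292 for hair keratins and 0.321 for the Lce family. The estimated correlation itself was 0.441 for hair keratins, which widens the error by construction. For epidermal proteases and inhibitors (0.00866), cell cycle (-0.0139) and neutrophil genes (-0.0848) it lay below the preset 0.01. These calls were lost too, so a higher correlation does not explain every loss. In this form of the test p rests on the 4 residual degrees of freedom, which raises p at any correlation. With the other settings 16 to 20 lists passed. Among lists with fewer calls, cholesterol synthesis lost its own with fry (0.165), dim probe sets removed (0.25) or a further quantile normalization (0.0841), neutrophil genes with the last of these (0.155), the averaged probe sets (0.0519) or the trend (0.0672), cell cycle without dim probe sets (0.193), and sebaceous genes with fry (0.0774) or without dim probe sets (0.0537).

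Over all alternatives, lists that had not passed gained a call in 16 instances, 6 of them for cytokines and 4 for junction genes, 2 for endothelium, with a further quantile normalization (0.0126) or without dim probe sets (0.0184), and 1 each for EGF receptor ligands (0.0119) and immediate early genes (0.0267) without dim probe sets, and the named genes lost theirs in 118 of their instances against 1198 unchanged in direction and call.

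No label says that the replicate numbers shared by the groups pair the mice, and the arrays do not settle it. Same-numbered arrays deviated together with correlations of 0.033, 0.135 and 0.0934. Arrays with different numbers gave -0.15 to 0.0705, and caNrf2 replicate 1 correlated best with control replicate 3. So few arrays can neither show nor exclude a pairing or a shared batch by number. With the replicate number as a block, 353 genes were higher and 236 lower, 320 and 185 of them among those called without it, and 18 lists passed.

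Directions turned only in results that passed no threshold. S100a8 gave -0.024 with array weights, and with 1 array left out S100a8 ran from -0.061 to 0.13 and S100a9 from -0.059 to 0.20. List directions turned with dim probe sets removed for basal keratinocytes (adjusted p = 0.896), T cells (0.883), adipocytes (0.906) and cartilage (0.626), with averaged probe sets for aryl hydrocarbon receptor targets (0.978), T cells (0.979) and nerve (0.979), with a further quantile normalization for T cells (0.901) and cartilage (0.901), with a trend for T cells (0.999), and with the block for aryl hydrocarbon receptor targets (0.951) and adipocytes (0.951). With 1 array left out, directions turned within ranges of 0.518 to 0.919 for the interferon response, 0.686 to 0.981 for aryl hydrocarbon receptor targets, 0.641 to 0.984 for the heat shock list, 0.153 to 0.981 for macrophages, 0.735 to 0.91 for T cells, 0.773 to 0.981 for adipocytes and 0.541 to 0.981 for nerve; the cause was not tested. Signal over background limits Gsta3, Slc7a11, Fbxo2, Sprr2f, Il24, Ces1c, Ces1f, Ces1g, Krtap31-1 and Krtap6-3, which lay within the level of Y-linked probe sets in at least 1 group.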

Other observations

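Some gene families, in part on the lists too, held more called genes than their size would give (hypergeometric test with Benjamini-Hochberg adjustment over 570 families, and genes chosen after their values were seen). Whether the probe sets of a family also detect its other members was not tested. Genes that share signal would repeat each other in these counts and p. Carboxylesterases, which hydrolyse esters of drugs and lipids, held 4 rises and 1 fall among 13 (adjusted p = 0.0299 for rises), but 2 of these, Ces1c and Ces1g, lay within the range of Y-linked probe sets in both groups and Ces1f in control skin. The remaining rise was Ces1h, by 1.45 ± 0.16 on the log2 scale. The Gstm family held 5 rises among 7 (adjusted p = 6.7e-05), 4 of them already counted as detoxification enzymes, with Gstm6, which stood on no list, rising by 2.02 ± 0.10.

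Lower families included Clca, membrane proteins once taken for chloride channels, with 3 falls among 8 (adjusted p = 0.0199) and Clca3a2 falling from 1465 ± 109 to 921 ± 63.0 (mean intensity ± SD). The homeobox genes Dlx, expressed in hair matrix and other epithelia, had 3 falls among 10 (adjusted p = 0.0334), with Dlx4 at -0.45 ± 0.07 (other probe set -0.18) and Dlx1 at -0.46 ± 0.09. The Dlx1 call was lost without any of 4 arrays, at adjusted p up to 0.0988. The fatty acid elongases Elovl had 3 falls among 7 (adjusted p = 0.0168), including Elovl3 and Elovl6 of the lipid lists. Against the fall of its family, Krtap31-1 rose from 21.1 ± 1.38 to 46.0 ± 9.45 (log2 fold change 1.10 ± 0.14; limma, adjusted p = 0.00171), from a control mean within the range of Y-linked probe sets, so the size is uncertain.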
